A study of Homo sapiens with 4 samples.

How the data were processed

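RNA was measured in 4 libraries of the cell line HTR8/SVneo, 2 from normoxia and 2 from cells kept in 2% oxygen for 12 h. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with an Illumina TruSeq RNA kit. The deposited table gives RPKM per library, per the name of its sheet. It also gives the authors' log2 fold change, p-value and adjusted p-value, per the file headers. HISAT2 2.1.0, StringTie 1.3.3b, DESeq2 and genome build hg38 are named, per the submitters' processing notes. Which tool made which column, the annotation, the use of strand, the normalization and the filters are not given in the sources used here.

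The table was tested before use. It holds 6390 rows with 6377 distinct symbols, and the largest p-value in the authors' deposited table is 0.0499, so rows were selected on it. The adjusted p-values in the authors' deposited table imply an adjustment over 14498 genes. An adjusted p under 0.05 is given for 5280 rows in the authors' deposited table, of which 2519 have a log2 fold change above 0, 2752 below 0 and 9 at 0. The authors' deposited log2 fold change equals the log2 ratio of mean RPKM + 1 in hypoxia over normoxia (largest difference 1.3e-15), so a positive value is higher in hypoxia although the header names normoxia first. In 19 rows RPKM is 0 in all 4 libraries, and 9 of these have an adjusted p under 0.05 in the authors' deposited table, so those p-values were not computed from the deposited RPKM. For 10 symbols with several rows, 23 rows in all, the rows of a symbol share a p-value in the authors' deposited table. No mitochondrial row is listed, and 9 rows have date-like names in place of symbols and were not named. Genes without a row were not analysed here. Of the symbols, 6128 were current, 158 were matched by an older name and 91 were unmatched. Coordinates are those of GENCODE on GRCh38, to which 6198 rows matched by symbol, chromosome and strand.

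The main test was limma 3.58.1 (R 4.3.3) on log2(RPKM + 1), with empirical Bayes moderation and a mean-dependent prior, two-sided, on the 5846 rows with a mean RPKM of at least 1; 544 rows were below that. P-values were adjusted by Benjamini-Hochberg at 0.05. Fold changes are differences of mean log2(RPKM + 1), a scale that understates those of low genes. The fit had 2 residual degrees of freedom and 3.07 prior degrees of freedom, and the median SE was 0.10. Testing genes that were selected on the same libraries makes the adjusted p-values too small. Read depth is unknown because RPKM does not return counts, so no counting interval is given. The rank correlation of the absolute log2 RPKM ratio with the size of the authors' deposited p-value was highest with the ratio centred at -0.33 (rho = 0.785, against 0.423 at 0), over 3190 rows with a mean RPKM of at least 10, with a bootstrap SD of 0.0048 over 100 draws of rows. The centre was -0.38 with a minimum mean RPKM of 1, -0.34 with 5 and -0.32 with 50, so the bootstrap SD understates its uncertainty. The centre at -0.33 is called the zero point and was applied to all tested rows.

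For 36 gene lists, fixed with the design and the rule for named genes before the data were examined, the members called higher and lower were counted over all genes and over the list alone. Lists with at least 3 tested members, 33 in all, were tested with limma's camera at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over lists. Of these, 11 passed, 0 passed with an estimated correlation, and 24 passed fry, which tests each list on its own. All rows had been selected for change on these same libraries, which can raise the count by fry. The rule named the 10 largest rises and the 10 largest falls among called genes whose groups do not overlap, up to 4 called members of each list with the largest change (up to 2 by level where none was called), and VEGFA, CA9, PGF and other fixed genes where listed. ITGB1, CDT1, E2F1, UBE2C, DDIT3, MMP14, MMP15, PLAT, ADAMTS1, HSPA1A, HSPA1B, GAPDH, PSMC2, PSMA3 and PSMA5 were named after their values were seen. On simulated data with the real means and spreads of the 5846 genes and 200 changed genes, limma recovered 31 of 67 changes of 0.5, 65 of 67 of 1 and 65 of 66 of 2 on the log2 scale, with 12 false calls. The simulated genes were not selected on a p-value, and far fewer were changed than were called in the real data. The recovery and the false calls therefore do not carry over to the real data. Camera, tested on simulated data too, called a planted list of 20 changed genes and did not call an unchanged list. Those genes were simulated independently, and none outside the planted list was changed, so this result does not carry over to the real data either. Alternatives tried were other pseudocounts, filters, scalings, priors and thresholds, a replicate block, leaving out each library, summing rows of a symbol, and, added after the data were seen, adjustment over 14498 genes, rescaling to the zero point, requiring the authors' adjusted p as well, leaving out rows with a library at 0, and a Fisher test of list directions. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest.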

Results

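The deposited table describes the transcriptome of HTR8/SVneo cells, an immortalised line derived from first-trimester extravillous trophoblast, the invasive cells of the human placenta. Cells were kept in normoxia or exposed to 2% oxygen for 12 h, and RNA-seq libraries were made from total RNA. There were 4 libraries, 2 from normoxia and 2 from hypoxia. The question was which transcripts differ between the conditions. The table gives RPKM (reads per kilobase of transcript, scaled to the mapped reads of the library) for 6390 rows, and every row carries a p-value under 0.05 in the authors' deposited table, so it is a list already selected for change, not the whole transcriptome. Read depth cannot be recovered from RPKM and is unknown here. The listed RPKM summed to 295974 and 294692 in the normoxia libraries and to 327794 and 329730 in the hypoxia libraries. On log2(RPKM + 1) the normoxia replicates correlated across genes at r = 0.987, the hypoxia replicates at r = 0.989, and libraries of different conditions at 0.936 to 0.944. Genes are not independent replicates, so these r values only describe the libraries. The labels do not say whether replicates were separate cultures, so limma's p-values of single genes measure only the spread between these libraries, which may be technical. Camera at the preset correlation, the Fisher tests, and the draws and binomial tests further below take genes or rows as their units. Their p-values measure the spread across genes, not between libraries.

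Transcripts of classical oxygen-responsive genes were higher in hypoxia and those of mitotic genes were lower. ANGPTL4, which encodes an inhibitor of lipoprotein lipase, went from 2.32 ± 0.215 RPKM to 67.8 ± 5.88 (mean ± SD, n = 2 per group), a log2 fold change of 4.37 ± 0.11 (SE). NDRG1, a stress-induced gene, rose from 58.6 ± 10.7 to 921.2 ± 41.6 RPKM. CA9, the cell-surface carbonic anhydrase, rose from 6.91 ± 0.229 to 82.9 ± 6.23 RPKM. DKK1, a secreted Wnt antagonist, fell from 98.3 ± 8.26 to 22.3 ± 2.43 RPKM, and CDC25C, the phosphatase that starts mitosis, fell from 17.9 ± 2.51 to 3.92 ± 0.552 RPKM.

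Of 5846 genes tested by limma, 3528 differed at an adjusted p under 0.05, with 1047 higher and 2481 lower in hypoxia, and 2318 did not pass. Of those that passed, 188 were higher and 386 lower by at least 1 on the log2 scale. Because the list was selected on these same libraries, its adjusted p-values are too small. Counting all 14498 genes that the authors' deposited table implies were adjusted together left 3064 calls, 763 higher and 2301 lower. The balance between higher and lower also depended on the scale. The p-values in the authors' deposited table were largest at a log2 ratio of -0.33, not at 0, so that the RPKM of a gene with no change in the authors' test lay 0.33 lower in hypoxia. Rescaling the hypoxia libraries to that point gave 4602 calls, of which 2718 were higher and 1884 lower. This raises all genes alike, so higher calls could hardly be lost; 597 of the lower calls no longer passed. Higher genes made up 29.7% of the calls as deposited, 59.1% after that rescaling, 48.8% after median centring, 47.4% after quantile normalization, 47.9% after trimmed mean scaling and 19.9% with libraries scaled to an equal sum. The groups did not overlap in 4631 of the tested genes (79.2%), against 33.3% by chance in unselected genes.

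**Figure D1:**
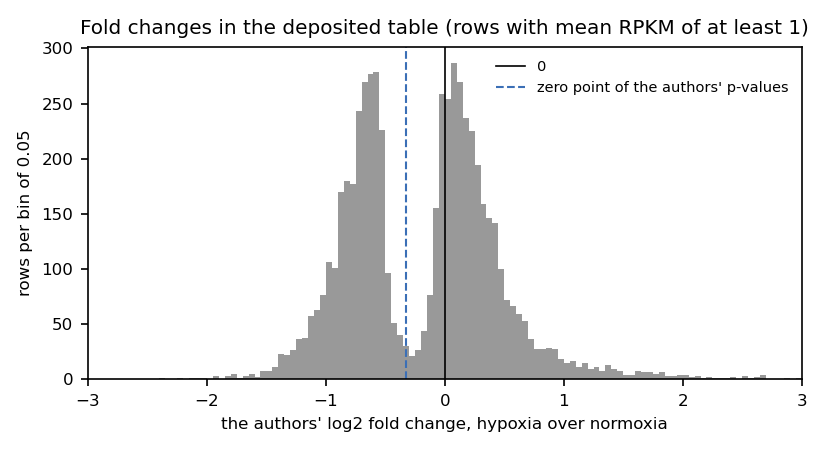
Histogram of the log2 fold change (hypoxia over normoxia) in the authors' deposited table, in rows per bin of 0.05, for 5845 of the 5846 rows with a mean RPKM of at least 1, the other being left out of every table of single genes; 9 rows lie outside the axis. Rows are scarce at the dashed line at -0.33, where the authors' p-values are largest, and not at the solid line at 0.

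**Figure D2:**
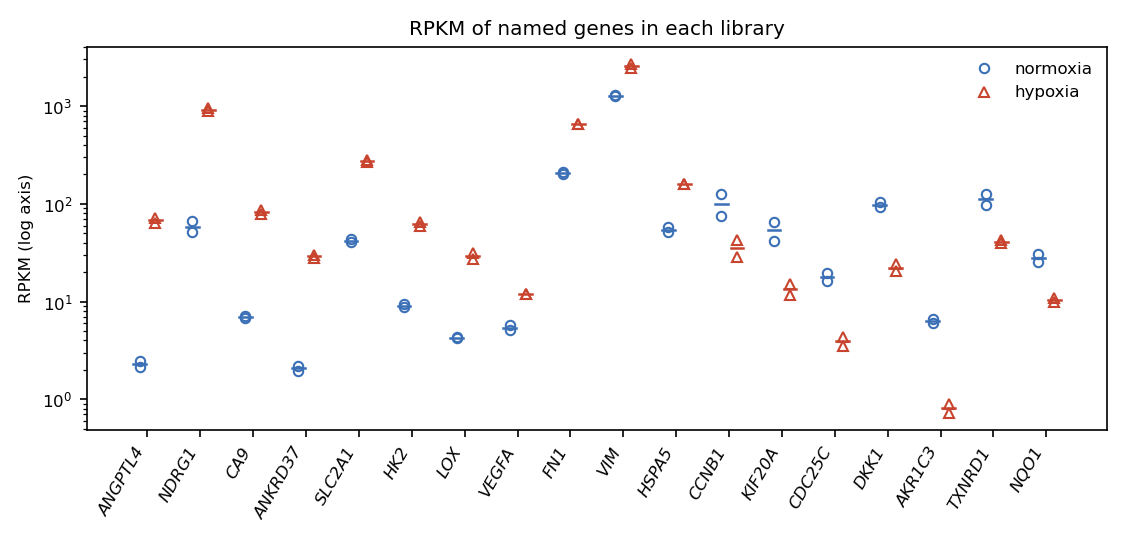
RPKM on a log axis for 18 named genes. Each open symbol is a library, circles for normoxia and triangles for hypoxia, with 2 per group, and each bar is a group mean; in each of these genes the hypoxia libraries lie on one side of both normoxia libraries.

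Tested genes of the fixed list of hypoxia-inducible genes outside glycolysis rose together. Of its 40 members 32 had a row and 28 were tested. Every list was cut in this way, the epithelial-mesenchymal list to 7 of 21 and trophoblast identity to 6 of 23, so unchanged members may be missing from the counts. Of the 28 tested members 28 rose and 0 fell, with a median log2 fold change of 1.25, and 28 rose when adjusted over the list alone. Beside ANGPTL4, NDRG1 and CA9, ANKRD37, an ankyrin repeat gene, rose from 2.07 ± 0.160 to 29.1 ± 1.56 RPKM, and STC2, which encodes a secreted glycoprotein, from 3.38 to 27.1 RPKM. VEGFA, which encodes the main angiogenic growth factor, rose by 1.01 ± 0.10 on the log2 scale, from 5.43 to 11.9 RPKM. In the list of glycolysis and glucose uptake 21 of 23 tested members rose and 0 fell, with a median of 1.04, and adjusted over the list alone the count was again 21. The glucose transporter SLC2A1 went from 41.9 ± 2.12 to 274.8 ± 8.98 RPKM and the transporter SLC2A3 from 19.1 to 106.8 RPKM. Hexokinase HK2 rose by 2.66 ± 0.09 on the log2 scale and enolase ENO2 by 1.78 ± 0.08. Camera, which compares a list with the other listed genes, gave an adjusted p of 8.4e-17 for the hypoxia-inducible list and 7.0e-13 for glycolysis, and each had an adjusted p = 0.231 with an estimated correlation. Among genes of oxygen sensing, 2 of 6 tested members rose and 2 fell, the same counts as when adjusted over the list alone, and 4 were higher and 2 lower after rescaling to the zero point (camera adjusted p = 0.620). The prolyl hydroxylase EGLN1 rose by 0.46 ± 0.10 and the transcriptional co-regulator CITED2 by 0.50 ± 0.11. The asparaginyl hydroxylase HIF1AN fell by 0.62 and the ubiquitin ligase scaffold CUL2 fell by 0.74 on the log2 scale. The limma call of EGLN1 was lost without normoxia replicate 1 or without hypoxia replicate 2, and that of CITED2 without normoxia replicate 2. HIF1A and EPAS1, the oxygen-regulated HIF subunits, have no row in the table and were not analysed here.

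**Figure D3:**
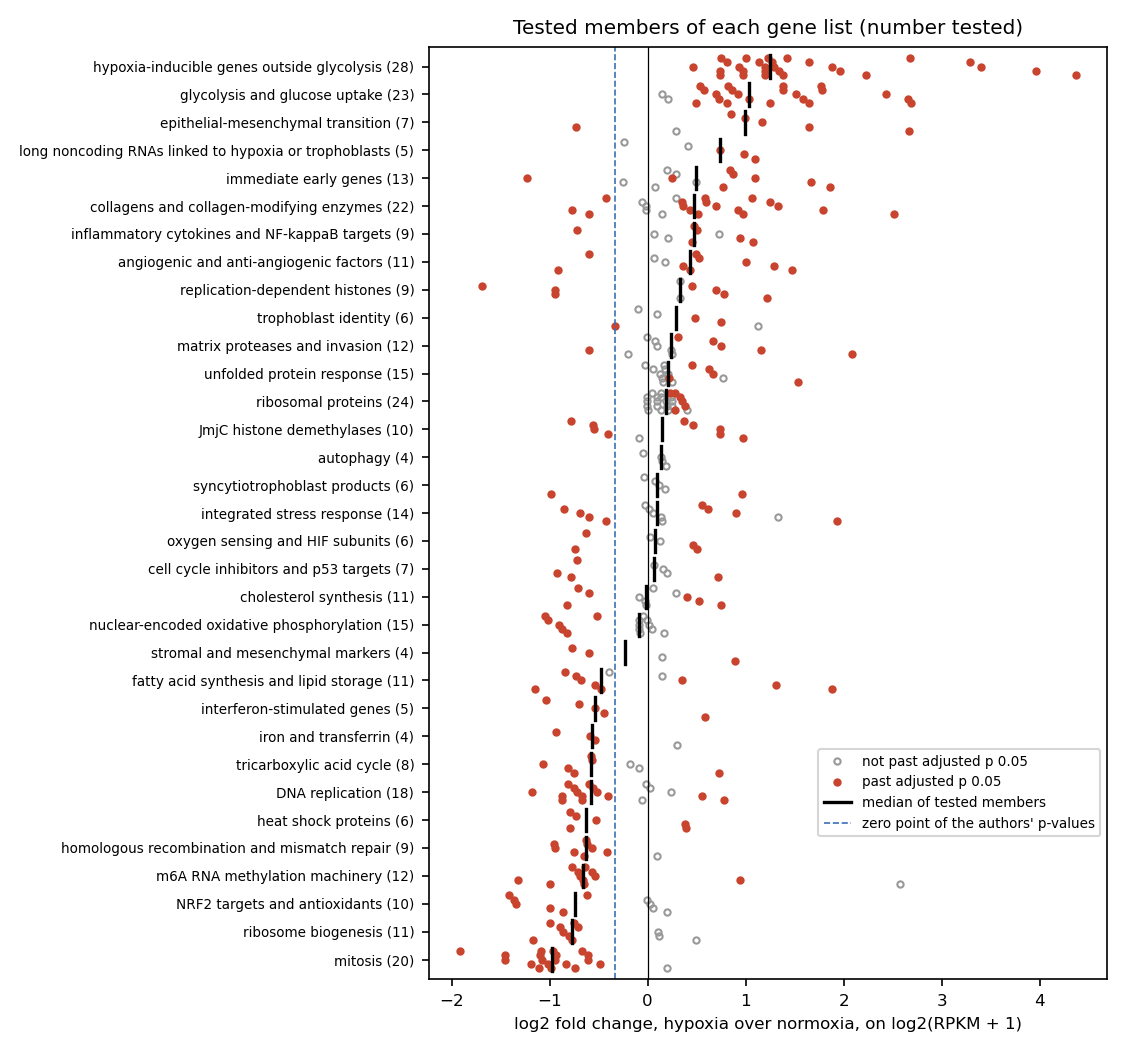
Log2 fold change (hypoxia over normoxia, on log2(RPKM + 1)) of the tested members of 33 fixed gene lists, with the number tested after each name. Filled points passed an adjusted p of 0.05 and open points did not, black bars are list medians, and the dashed line marks -0.33; the hypoxia-inducible and glycolysis lists lie to the right with medians of 1.25 and 1.04, and mitosis to the left with -0.98.

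Among genes of the collagen, invasion, epithelial-mesenchymal and angiogenic lists, more rose than fell. Of 22 tested collagens and collagen-modifying enzymes 14 rose and 3 fell, with a median of 0.47. The lysyl oxidase LOX, which cross-links collagen, rose from 4.28 ± 0.114 to 29.2 ± 3.19 RPKM, the prolyl hydroxylases P4HA1 and P4HA2 by 1.79 ± 0.08 and 1.25 ± 0.13 on the log2 scale, and PLOD2, which hydroxylates collagen lysines, by 1.33 ± 0.09. COL3A1, which encodes a fibrillar collagen, fell by 0.77. In the list of matrix proteases and invasion 5 of 12 members rose and 1 fell, against 10 and 1 after rescaling to the zero point, which include the proteases MMP14, MMP15, PLAT and ADAMTS1. On the deposited scale no protease passed: SERPINE1, the plasminogen activator inhibitor, rose from 81.0 ± 2.23 to 347.3 ± 4.28 RPKM, PLAUR, the urokinase receptor, by 1.16 ± 0.07, and the integrins ITGA5, ITGB4 and ITGB1 by 0.75, 0.67 and 0.31. Of 7 tested genes of the epithelial-mesenchymal transition 5 rose and 1 fell, among them CCN2 (listed under its older name CTGF) by 2.67 ± 0.10, fibronectin FN1 by 1.65 ± 0.06, TGFB2 by 1.17 ± 0.19 and vimentin VIM by 1.00 ± 0.07. The transcription factors SNAI1, SNAI2, ZEB1 and ZEB2 and the cadherins CDH1 and CDH2 were not analysed here, having no row. Among angiogenic and anti-angiogenic factors 7 of 11 rose and 2 fell, with the vasoconstrictor peptide gene EDN1 up by 1.47 ± 0.11 and ADM, which encodes the vasodilator adrenomedullin, by 1.29 ± 0.09. The co-receptors NRP1 and ENG fell by 0.92 and 0.60. PGF, the placental growth factor gene, stood at 10.4 ± 0.413 RPKM in normoxia and 10.9 ± 0.261 in hypoxia and did not pass (limma adjusted p = 0.574; 0.0175 after rescaling to the zero point of the authors' p-values). FLT1 has no row. Adjusted over the list alone, 15 collagen genes rose and 3 fell, and the counts of the other lists were 5 and 1, 5 and 1, and 7 and 2. Camera gave adjusted p-values of 9.8e-05 for collagens, 0.00919 for matrix proteases, 0.00290 for the epithelial-mesenchymal list and 0.0151 for angiogenic factors, and each of these lists had an adjusted p = 0.434 with an estimated correlation. After rescaling to the zero point the angiogenic list no longer passed. By a Fisher test of the members on either side of the zero point, collagens passed (adjusted p = 0.0223), while matrix proteases, the epithelial-mesenchymal list and angiogenic factors did not (0.0530, 0.269 and 0.269). Here and for the other lists this test was not matched on RPKM or GC content. Rows low in either lay below the zero point more often, so a pass may reflect level or GC content.

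Mitotic genes were lower in hypoxia. Of 20 tested members of the mitosis list 0 rose and 19 fell, with a median of -0.98. KIF20A, a kinesin of cytokinesis, fell from 54.0 ± 16.9 to 13.3 ± 2.38 RPKM and the cyclin CCNB1 from 100.4 ± 35.6 to 35.5 ± 9.45 RPKM. The kinase AURKA fell by 1.46 and the spindle gene ASPM fell by 1.19 on the log2 scale, and the limma call of AURKA was lost without normoxia replicate 1 or without normoxia replicate 2. UBE2C did not pass, and adjusted over the list alone it counted as higher while the 19 others fell. Camera gave an adjusted p of 3.2e-04 for mitosis, with an adjusted p = 0.434 with an estimated correlation. Of 18 tested genes of DNA replication 12 fell, among them the helicase-complex genes GINS3 at -1.18 ± 0.10 and GINS1 at -0.88 ± 0.14 and the loading factor CDC6 at -0.81 ± 0.16, and 2 rose, the licensing factor CDT1 and the transcription factor E2F1. Homologous recombination and mismatch repair had 8 of 9 members lower and 0 higher, with XRCC2 at -0.96 ± 0.10, RAD51C at -0.95 ± 0.19 (lost without normoxia replicate 1) and the mismatch repair genes PMS2 and MLH1 at -0.75 ± 0.10 and -0.65 ± 0.09. Ribosome biogenesis had 8 of 11 members lower and 0 higher, including WDR12 at -1.17 ± 0.20 and POLR1A, a subunit of RNA polymerase I, at -0.89 ± 0.10. The counts of these 3 lists were the same when adjusted over the list alone, and none was called by camera (adjusted p = 0.177, 0.0604 and 0.137), although the repair list passed the Fisher test (adjusted p = 0.0496). After rescaling, DNA replication had 6 higher and 7 lower, the repair list 1 higher and 6 lower, and ribosome biogenesis 3 higher and 8 lower. Of 7 tested cell cycle inhibitors and p53 targets 1 rose and 3 fell, the same counts as when adjusted over the list alone, but 4 were higher and 3 lower after rescaling (camera adjusted p = 0.910): CDKN1C rose by 0.72 ± 0.11, whereas the inhibitor CDKN1B fell by 0.93 and TIGAR by 0.78.

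Stress-response genes moved in different directions. Of 15 tested genes of the unfolded protein response 5 rose and 0 fell, against 4 adjusted over the list alone and 15 after rescaling. The endoplasmic reticulum chaperone HSPA5 rose from 54.5 ± 4.18 to 160.0 ± 0.981 RPKM, HSP90B1 by 0.63 ± 0.12, the co-chaperone DNAJB9 by 0.67 ± 0.10 and calreticulin CALR by 0.45 ± 0.08. Immediate early genes had 7 of 13 members higher and 1 lower, with the phosphatase DUSP1 up by 1.86 ± 0.09, the nuclear receptor NR4A1 by 1.66 ± 0.10 and the transcription factor KLF2 at -1.23 ± 0.09. In the list of inflammatory cytokines and NF-kappaB targets 5 of 9 rose and 1 fell, against 8 and 1 after rescaling. LIF rose by 1.07 ± 0.11 and NFKBIZ by 0.95 ± 0.09, while IL1B, at 2.32 RPKM in normoxia, fell by 0.72. Both lists had the same counts adjusted over the list alone. Camera gave adjusted p-values of 0.00125 for the unfolded protein response, 0.00210 for immediate early genes and 0.0173 for the inflammatory list, and each had an adjusted p = 0.434 with an estimated correlation. The inflammatory list no longer passed after rescaling to the zero point or by the Fisher test (adjusted p = 0.144). The integrated stress response was split, with 4 of 14 members higher and 4 lower, also when adjusted over the list alone, and with 9 higher and 2 lower after rescaling (camera adjusted p = 0.189). PPP1R15A, a phosphatase subunit that reverses eIF2-alpha phosphorylation, rose by 1.94 ± 0.08 and the amino acid transporter SLC7A5 by 0.90 ± 0.08, while the cystine transporter SLC7A11 fell by 0.86 and SESN2 by 0.69. DDIT3 stood at 12.6 RPKM in hypoxia replicate 1 and at 50.6 RPKM in replicate 2, and did not pass.

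Antioxidant genes under the transcription factor NRF2 included some of the larger falls. In that list 0 of 10 tested members rose and 6 fell, also when adjusted over the list alone, with 4 higher and 4 lower after rescaling. They included TXNRD1, thioredoxin reductase, at -1.41 ± 0.14 and the quinone reductase NQO1 at -1.35 ± 0.12. PRDX1, a peroxiredoxin, was at -1.37 ± 0.42, a call that limma lost without normoxia replicate 1, without hypoxia replicate 2 and after rescaling. Camera did not call the list (adjusted p = 0.318). Of 6 heat shock proteins 2 rose, the near-identical HSPA1A and HSPA1B, whose reads cannot be told apart with certainty, and 4 fell, among them HSPA8 by 0.73 and HSPA4 by 0.79, against 0 and 4 with libraries scaled to an equal sum. Interferon-stimulated genes had 1 of 5 higher, IRF7, and 4 lower, including IFI35 at -1.04 ± 0.09, against 1 and 2 after rescaling. Of 4 genes of iron handling 0 rose and 3 fell, with the iron transporter SLC11A2 at -0.94 ± 0.11, against 1 and 2 after rescaling. Of 4 autophagy genes 0 rose and 0 fell, and GABARAP stood at 140.6 ± 13.3 and 155.0 ± 4.20 RPKM. These 4 lists had the same counts adjusted over the list alone, and camera called none (adjusted p = 0.565, 0.332, 0.380 and 0.318). After rescaling the autophagy list had 3 members higher.

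Genes of mitochondrial metabolism and lipid synthesis were mixed. Nuclear-encoded oxidative phosphorylation had 0 of 15 tested members higher and 6 lower, among them NDUFB3 at -1.04 ± 0.23 and NDUFS1 at -0.87 ± 0.15, but after rescaling 8 were higher and 3 lower (camera adjusted p = 0.440). Mitochondrially encoded transcripts have no row in the table. In the tricarboxylic acid cycle 1 of 8 rose, IDH2 by 0.73 ± 0.07, and 5 fell, including OGDH by 0.75 and IDH1 by 0.81; after rescaling 2 were higher and 2 lower (camera adjusted p = 0.318). Cholesterol synthesis had 3 of 11 higher and 3 lower, with INSIG1 up by 0.74 ± 0.09 and ACAT2 at -0.83 ± 0.08, and after rescaling 7 were higher and 3 lower, against 1 and 4 with libraries scaled to an equal sum (camera adjusted p = 0.595). In fatty acid synthesis and lipid storage 3 of 11 rose and 6 fell, but 4 were higher and 3 lower after rescaling (camera adjusted p = 0.949). The risers included the lipid droplet genes HILPDA by 1.88 ± 0.10 and PLIN2 by 1.31 ± 0.12, and the falls included SREBF1, a regulator of lipid synthesis, by 1.15 and fatty acid synthase FASN by 0.84. The counts of these lists were the same adjusted over the list alone.

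Genes acting on RNA and chromatin also differed. Of 12 tested members of the m6A RNA methylation machinery 1 rose and 10 fell, with a median of -0.66 (camera adjusted p = 0.127; Fisher adjusted p = 0.0371). The riser was the demethylase ALKBH5, from 98.7 ± 1.48 to 191.1 ± 5.65 RPKM. Named and list genes otherwise run in falling order of log2 fold change in the authors' deposited table. ALKBH5, at 0.946, stands there between TIE1 at 0.428 and MSMO1 at 0.405, so its value is uncertain. The m6A-binding protein gene IGF2BP3 fell by 1.32, RBM15B by 0.99 and the methyltransferase METTL3 by 0.77, and after rescaling 1 member was higher and 5 lower. JmjC histone demethylases, oxygen-dependent enzymes, had 5 of 10 higher and 4 lower, against 5 and 1 after rescaling or quantile normalization and 3 and 4 with libraries scaled to an equal sum (camera adjusted p = 0.362), with KDM3A up by 0.97 ± 0.11, KDM4B by 0.74 ± 0.10 and KDM4A at -0.79 ± 0.08. Among hypoxia- and trophoblast-linked long noncoding RNAs 3 of 5 rose and 0 fell (camera adjusted p = 0.0632), MEG3 by 1.10 ± 0.13, H19 by 0.98 ± 0.14 and MIR210HG by 0.74 ± 0.16, the last lost without normoxia replicate 1. These 3 lists kept their counts when adjusted over the list alone. Replication-dependent histones had 4 of 9 higher and 3 lower, or 6 and 3 adjusted over the list alone or after rescaling and 3 and 3 with libraries scaled to an equal sum (camera adjusted p = 0.217), with HIST1H1E up by 1.21 ± 0.18 and HIST1H4H at -1.69 ± 0.23. Histone genes are near-identical copies, so their individual values are uncertain. Of 24 tested ribosomal proteins 6 rose, 0 fell and 18 did not pass, or 5 rose and 0 fell adjusted over the list alone. RPL8 was up by 0.38 ± 0.07 and RPL19 by 0.35 ± 0.07, calls lost without hypoxia replicate 1 and without hypoxia replicate 2 respectively. Camera called this list (adjusted p = 7.9e-04), with an adjusted p = 0.434 with an estimated correlation, but its direction followed the scale. The counts were 22 higher and 0 lower after rescaling to the zero point, 1 and 0 with libraries scaled to an equal sum, and 0 and 3 after quantile normalization. Ribosomal proteins have many processed pseudogenes that can share their reads.

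Few markers of trophoblast identity or of other cell types had a row in the table. Of 6 tested trophoblast identity genes 2 rose, ITGA5 and the Wnt inhibitor NOTUM (by 0.48 ± 0.10), and 1 fell, the receptor MET at -0.33 ± 0.10. MET lay at the zero point of the authors' p-values, was at -0.02 after rescaling, and lost its call without normoxia replicate 2 or without either hypoxia replicate. NOTUM lost its call without hypoxia replicate 2. After rescaling 4 were higher and 0 lower, and adjusted over the list alone the counts were 3 and 1 (camera adjusted p = 0.189). HLA-G, the class I molecule of extravillous trophoblast, has no row. Of 6 syncytiotrophoblast products 1 rose, KISS1 by 0.96 ± 0.11 at a level of 4.17 RPKM in hypoxia, and 1 fell, HSD17B1 at -0.98 ± 0.13, while after rescaling 4 were higher and 1 lower (camera adjusted p = 0.362). Stromal and mesenchymal markers had 1 of 4 higher, TAGLN by 0.90 ± 0.07, and 2 lower, COL3A1 and ENG, and 2 higher and 2 lower after rescaling (camera adjusted p = 0.854). The last 2 lists had the same counts adjusted over the list alone. For the oxygen sensing, cell cycle inhibitor, cholesterol and stromal lists the median, the mean and the camera direction did not share a sign. Endothelial markers had 2 tested members, with TIE1 up by 0.43 ± 0.12, a call lost without normoxia replicate 1 and without hypoxia replicate 1, and leukocyte markers had 1, CD68, which rose by 0.59 ± 0.13. Both lists were too small for camera, and their counts of 1 and 1 were the same adjusted over the list alone.

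Outside the lists, NPPB, which encodes the natriuretic peptide BNP, went from 0.548 ± 0.775 to 15.8 ± 2.96 RPKM and NOG, a BMP antagonist, from 1.43 to 18.3 RPKM. AKR1C3, an aldo-keto reductase, fell from 6.33 ± 0.333 to 0.812 ± 0.117 RPKM, PPP1R10 from 8.90 to 1.15, CLCN5, a chloride channel gene, from 10.8 to 1.27, EID2 from 13.2 to 2.96 and SH3BP5L from 31.7 to 8.22 RPKM. On GRCh38, in the reference annotation GENCODE, ANGPTL4 spans positions 8363289 to 8374373 of chromosome 19, NDRG1 133237171 to 133302022 of chromosome 8, CA9 35673856 to 35681159 of chromosome 9 and DKK1 52314296 to 52318042 of chromosome 10. The fixed rule also named YAE1D1 at a log2 fold change of -2.14 ± 0.15, GTF3C2-AS1 at -3.33 ± 0.19 and LIX1L-AS1 at 2.83 ± 0.23. The last 2 are antisense genes, and no use of strand in the counting is stated in the sources used here, so their reads may be those of the partner gene and their values are uncertain. SNORD14E, a small nucleolar RNA inside the HSPA8 gene, went from 0.0985 ± 0.139 to 14.1 ± 5.75 RPKM, and its reads overlap its host.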

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

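The alternatives chosen after the data were seen are adjustment over 14498 genes, rescaling to the zero point, requiring the authors' adjusted p too, leaving out rows with a library at 0, and the Fisher test of list directions; the others were planned. Among single named genes under all alternatives, 2879 comparisons kept direction and side of the threshold, 162 lost the call, 10 gained it and 0 reversed; among lists 359 kept both, 17 lost the call, 19 gained it and 1 reversed. The correlation of normoxia replicates was 0.981 with pseudocount 0.1 and 0.985 by Spearman. Read depth is unknown, so what it limits cannot be stated. A replicate block gave 3493 genes changed and 12 lists. The labels share only a number, and the deviations of same-numbered libraries correlated at -0.10.

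For genes lower in hypoxia, a minimum mean RPKM of 5 gave 1533, with fewer genes tested. For genes higher in hypoxia, scaling libraries to an equal sum gave 648, median centring 2110, quantile normalization 1625, trimmed mean scaling 2106 and rescaling to the zero point 2718; the cause was not tested. Limma's treat at a fold of 1.2 gave 476 genes higher. Requiring an absolute log2 fold change of at least 1 left 574 genes changed, 188 genes higher in hypoxia and 386 genes lower in hypoxia, by construction. Of gene lists called by camera, 0 remained with the correlation estimated from the data, and fry called 24. The estimate was above the preset 0.01 for collagens (0.352), mitosis (0.292), the epithelial-mesenchymal list (0.152) and matrix proteases (0.051). It was below 0.01 for the other called lists, at -0.0056 for the hypoxia-inducible list and -0.038 for glycolysis. A higher correlation among members therefore does not account for the loss of those other lists. The cause was otherwise not tested. The list cholesterol synthesis, at a median of -0.019, passed fry in the opposite direction to camera (fry adjusted p = 0.0147). That median lies below 0, with which fry compares a list. It lies above the median of all tested rows, -0.063, and camera compares a list with the other genes, so the 2 directions need not conflict. Without 1 library in turn, where the lone sample is assumed to vary like the other group, limma gave 2935 to 3287 genes changed, 752 to 895 genes higher in hypoxia, 2178 to 2422 genes lower in hypoxia and 11 to 12 gene lists called by camera. The noncoding RNA list gained its call without normoxia replicate 1 or hypoxia replicate 1, and the repair list without hypoxia replicate 2.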

Other observations

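The gene families of the next paragraph, and the tests of read share, of sampling noise in small RNAs, of transcript length against RPKM level and of the GC slope, the draws matched on GC content and the counts by host, were chosen after the values were seen; the other tests were chosen before.

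Of 27 gene families, 12 passed a Fisher test against the zero point, and 6 of these also passed 10000 draws matched on mean RPKM and draws matched on GC content as well (two-sided, adjusted over families), 4 with more members below it than the draws and 2 with fewer. Subunits of the proteasome, the complex that degrades ubiquitinated proteins, were lower: of 25 tested by limma 0 rose and 19 fell, against 4 and 14 after rescaling to the zero point and 1 and 17 after quantile normalization. PSMC2 stood at -1.30, PSMA3 at -1.29 and PSMA5 at -1.19. Below the zero point lay 76.0% of them, against 29.8% in draws matched on mean RPKM and 38.3% matched on both (Fisher adjusted p = 0.0105; draws 0.00135 and 0.00108). Among 168 zinc finger genes named ZNF, 14 rose and 121 fell, or 33 and 106 after rescaling and 30 and 71 after quantile normalization, and 75.0% lay below the zero point, against 59.1% in draws; of the 167 with a known GC content 74.9% did, against 62.1% (draws 0.00135 and 0.00108). Single-exon protein-coding genes lay below it in 69.1%, against 49.6% in draws matched on mean RPKM and 44.4% matched on both (Fisher adjusted p = 1.0e-05, draws 0.00135 and 0.00108). Of all tested rows 44.9% lay below it. Kinesins, the motors of the spindle and of transport, had 2 of 22 higher and 16 lower, or 5 and 14 after rescaling (Fisher adjusted p = 0.0290, draws 0.0229 and 0.0297). Below the zero point lay 72.7% of the kinesins, against 43.6% in draws matched on mean RPKM and 45.1% matched on both. Fewer genes named TMEM lay below it, 28.0% against 45.2% in draws matched on mean RPKM (Fisher adjusted p = 0.0105, draws 0.00972 and 0.0117). Of the 80 with a known GC content 26.25% did, against 41.5% in draws matched on both. The direction of the TMEM calls followed the scale. Of 82 tested by limma 13 rose and 21 fell, against 51 and 18 after rescaling and 10 and 22 with libraries scaled to an equal sum. The snoRNA genes, also with fewer members below it, are described below. Of 7 snoRNA host genes named SNHG 6 rose and 0 fell, at a median of 0.66, or 7 and 0 after rescaling (Fisher adjusted p = 0.0429), but neither kind of draw passed (0.209 and 0.177). Collagen genes named COL likewise passed the Fisher test (adjusted p = 0.0416) but neither kind of draw (0.137 and 0.342). Ribosomal protein genes passed the draws matched on both (0.00108) but not those matched on mean RPKM alone (0.137).

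The authors' p-values were largest at a log2 RPKM ratio of -0.33, not 0. With rows split into 3 equal bins, the zero point of the longest transcripts lay 0.03 above that of the shortest (SD 0.0116), and that of the highest GC content differed by -0.01 (SD 0.0113) from the lowest. This leaves bias by length or GC content open, and the bound of 0.10 set in advance was wrong, because the p-values come from the same reads and would move with them, as the share of these rows below the zero point differed between the outer bins by 7.84 points for length (Fisher p = 1.1e-04) and 30.5 for GC content (a cutoff of 10 points, tried first, would have excluded length). A larger share of reads taken by a few abundant genes, such as GAPDH at 1.63% of listed RPKM in normoxia and 4.18% in hypoxia, may contribute. It would need the listed rows to hold 69.2% of normoxia reads, and annotated lengths allow 31.0% to 81.6%, so it cannot be told apart from a difference in the authors' normalization, and no biological explanation was tested.

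Of 50 rows for snoRNA and miRNA genes, 48 lay above the zero point, 2 did not, and their median log2 fold change in the authors' deposited table was 1.55. Above it lay 35 of 36 snoRNA rows and 13 of 14 miRNA rows. The miRNA genes did not pass the draws matched on mean RPKM and GC content (adjusted p = 0.177). Sampling noise in short rows would place the 50 rows on both sides about equally, and the exact binomial p was 2.3e-12, or 2.8e-09 with rows joined by host, 37 of 39 above, in a class noticed for its direction. Higher host transcripts would raise both alike, but the log2 fold changes in the authors' deposited table exceeded those of listed hosts by a median of 1.11, in 29 of 29 pairs. Some pairs share a host, so the pairs are not independent. All rows were selected on the authors' p-value, and a short row with few reads passes only with a large change. The excess may thus be partly built in, so this comparison does not exclude higher host transcripts. A difference in the recovery of short RNA between libraries stays open and was not tested, as does an effect of hypoxia.

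Rows at low RPKM lay below the zero point more often, 64.6% in the lowest of 3 equal bins and 24.4% in the highest, and rows of low GC content too, 62.5% against 23.8%. The level difference stayed at 31.4 points or more within bins of transcript length and at 23.8 or more within bins of GC content. Among rows at least 0.7 from the zero point it was 49.5. The bins used the mean of all 4 libraries, so a rise moves a row to a higher bin and a fall to a lower one. This coupling can add to the difference, most among large changes, by an amount not tested. Length, GC content and selection of small changes are therefore not excluded as its whole cause. The fold change rose by 0.195 per 10 points of GC (SE 0.00939), while replicates differed by slopes of 0.0753 in normoxia and -0.0558 in hypoxia. With 2 libraries per group, a GC bias of the libraries and an effect of hypoxia on genes of low GC content cannot be told apart.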
